A study of Danio rerio with 12 samples.

How the data were processed

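RNA was measured by sequencing in 12 libraries of adult wild-type zebrafish testis tissue incubated for 48 h with trilostane, of which 6 also received Fsh. Per the labels' protocols, total RNA was isolated with a miRNeasy kit, its integrity was checked on an Agilent chip, and the libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, CASAVA 1.8, STAR 2.3 and HTSeq were used and the genome build was Zv9; the annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. The deposited values are whole-number counts per gene for 33737 Ensembl gene IDs in every library, not normalized, as the values themselves show, and they hold no entries for unassigned reads. Genes that overlap an antisense partner or share reads with a near-identical copy are therefore uncertain.

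A table of symbols named 21939 of the 33737 IDs. Among these, 1342 symbols are shared by 3305 IDs, mostly both copies of a duplicated zebrafish gene under a human-style name, so such genes are printed with their ID. No annotation of the same IDs with positions was used, so coordinates, gene lengths and GC content are not given.

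Counts were analysed in R 4.3.3. The test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) with TMM normalization, on the 19317 genes that filterByExpr kept by group, with no covariates and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. TMM factors ran from 0.891 to 1.05. Levels are counts-per-million (CPM) scaled by TMM, as mean ± SD over 6 libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Every adjusted p of a single gene comes from edgeR unless another tool is named.

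A set of 29 gene lists for testis cell types, other cell types of the tissue and pathways was written before the data were examined, as were the tests, their alternatives and the rule for named genes. Of 843 list entries, 701 matched the symbol table, 203 of them through a symbol that both copies share, which brought 681 gene IDs into the lists; 142 entries did not match. The lists overlap: igf3, insl3, inha and gsdf each stand in more than 1 list. All Leydig cell entries except insl3 and lhcgr also stand in the steroid hormone synthesis list. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 29 lists, each of which had at least 5 tested members; beside it stand camera with an estimated correlation and fry. fry asks whether a list's genes move, on balance, in a single direction, or in either direction in its mixed form, and does not compare the list with other genes.

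Named genes followed a rule. The genes fshr, lhcgr, igf3, insl3, amh, gsdf, star, cyp17a1, cyp11a2 and hsd3b1 were named whatever their result; the table has no cyp11a2, so both genes named CYP11A1 took its place. The rule added the 8 largest rises and 8 largest falls among called genes with a symbol that is not a clone name, a mean of at least 1 CPM and all 6 Fsh libraries on the same side of the control mean. From each list it took up to 4 called members in order of p, or the member with the smallest p where none was called. This gave 56 genes, 29 of them called.

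Library totals, genes detected and the share of counts in the 10 most abundant genes were compared between the groups. The shares of protein-coding mitochondrial genes and of red blood cell genes were compared as well. The test was an exact two-sided permutation test over all 924 arrangements, with scipy 1.17.1 in Python 3.11.15, adjusted over the 5 measures. Each library's total sets a floor: a count of 0 allows up to 3 counts, which is 0.259 to 0.641 CPM depending on the library, and such floors cover counting error only.

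Replicate libraries were compared before they were averaged. Every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom between 5.41 and 43.1 over the genes tested, and log2 CPM correlated between 0.909 and 0.984 across genes, which are not independent. The submitters describe the 6 libraries of a group as biological replicates. Whether libraries of equal number share a fish is not given in the sources used here, and the number was not used as a block.

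The pipeline was tested on simulated counts with the real means, dispersions and library sizes of this comparison, with 200 genes changed, in a step that tested 19080 genes. It recovered 9 of 65 genes changed 1.5-fold, 37 of 67 changed 2-fold and 64 of 65 changed 4-fold, and 4 of its 114 calls were unchanged genes. A simulated list of 20 genes raised 1.5-fold was called and none of 28 unchanged lists were, in data simulated without correlation between genes.

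Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, the replicate number as a block, a robust fit, a test against a 1.5-fold change and the omission of each library in turn. A fit with the mean of the leukocyte list as covariate was added after seeing the data, as was an exact permutation test of the mean log2 CPM of T and NK cell markers. Figures were drawn with matplotlib 3.10.9.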

Results

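The data are gene counts from 12 libraries of adult zebrafish testis tissue, all kept for 48 h with trilostane, an inhibitor of steroid hormone synthesis. The control group of 6 libraries had trilostane alone. The Fsh group of 6 libraries also had Fsh, the pituitary follicle-stimulating hormone, whose receptor is found on Sertoli cells and, in zebrafish, also on Leydig cells. Control libraries 1 to 6 held 4695095, 11497588, 8810253, 8389988, 7953508 and 8008154 counts. Fsh libraries 1 to 6 held 11367899, 6735718, 8680450, 8097230, 10458202 and 9563808 counts. The totals did not pass a test between the groups (exact permutation test, two-sided, p = 0.433, adjusted p = 0.524 over 5 measures). Genes with at least 1 count averaged 26004 ± 679 in controls and 26370 ± 343 with Fsh (SD, n = 6 each; exact permutation test, p = 0.271, adjusted p = 0.451).

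The comparison asks which testis genes differ with Fsh while steroid production is inhibited. With Fsh, igf3, a gonadal insulin-like growth factor of Sertoli cells, rose 4.42-fold (log2 fold change 2.14 ± 0.34 SE, n = 6 per group), and insl3, a peptide hormone of Leydig cells, rose 4.55-fold (2.19 ± 0.37). The Sertoli cell genes gsdf (gonadal soma derived factor) and inha (the inhibin alpha subunit) rose 6.60-fold (2.72 ± 0.60) and 6.24-fold (2.64 ± 0.54). The matrix gene FN1 (ENSDARG00000006526), a fibronectin, rose 3.24-fold (1.70 ± 0.25). Immune genes were among the largest falls: tlr18, a Toll-like receptor, fell 5.11-fold (−2.35 ± 0.37), the chemokine ccl34b.4 fell 4.13-fold (−2.05 ± 0.33) and ifng1, the cytokine interferon gamma, fell 4.71-fold (−2.24 ± 0.51). In all, 315 of 19317 tested genes changed (edgeR, adjusted p under 0.05), 167 higher and 148 lower, and 173 of them by more than 2-fold. The levels of 373 genes (1.93%) did not overlap between the groups, where chance gives 0.216%.

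Of 21 Sertoli cell genes tested, 5 rose and none fell; adjusted over the list alone, 9 were higher and 1 lower. The gene igf3 went from 1.74 ± 0.87 to 8.01 ± 2.80 CPM (adjusted p = 0.00819), and all 6 Fsh libraries lay above the control mean, as they did for GJA1, inha and gsdf. The gene inha went from 4.62 ± 4.23 to 29.3 ± 13.4 CPM (adjusted p = 0.0318), and gsdf from 17.4 ± 15.9 to 116 ± 57.3 CPM (adjusted p = 0.0418). Each of these missed the threshold without any 1 of 8 libraries, at adjusted p values up to 0.0769 for inha and 0.0977 for gsdf. With the mean of the leukocyte list as a covariate, a fit added after seeing the data, igf3 passed (adjusted p = 0.0322) and inha and gsdf did not (adjusted p = 0.0768 and 0.126). Their log2 fold changes went from 2.14 ± 0.34 to 1.97 ± 0.38 for igf3, from 2.64 ± 0.54 to 2.27 ± 0.58 for inha and from 2.72 ± 0.60 to 2.50 ± 0.77 for gsdf, so most of each rise remained. A robust fit also ended the call of gsdf (adjusted p = 0.0614). GJA1, the gap junction protein connexin 43, rose from 37.3 ± 6.32 to 72.2 ± 18.2 CPM (0.95 ± 0.18, adjusted p = 0.0196, and 0.0574 without control library 5). The anti-Müllerian hormone gene amh averaged 32.1 ± 19.4 and 115 ± 40.3 CPM but did not pass (1.85 ± 0.49, adjusted p = 0.0728). Without Fsh library 1 or control library 3 it passed, at adjusted p = 0.0371 and 0.0381. The receptor gene FSHR averaged 22 ± 2.51 and 20.4 ± 3.75 CPM (−0.11 ± 0.14, adjusted p = 0.726). The Sertoli list passed as a set, upwards, in camera at the preset correlation (median log2 fold change 0.31, adjusted p = 0.000237) and in fry (adjusted p = 0.0223). It did not in camera with an estimated correlation (adjusted p = 0.284).

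Of 11 Leydig cell genes tested, 2 rose and none fell, and 7 were higher adjusted over the list alone. The hormone gene insl3 went from 42.7 ± 23.1 to 195 ± 72.3 CPM (adjusted p = 0.0118). HSD11B2, an enzyme that makes 11-keto steroids, among them the main fish androgen, went from 16.5 ± 17.8 to 124 ± 85.0 CPM (2.90 ± 0.62, adjusted p = 0.0358). It missed the threshold without any 1 of 9 libraries, at adjusted p values up to 0.0847. With the leukocyte covariate insl3 passed (1.70 ± 0.37, from 2.19 ± 0.37; adjusted p = 0.0479). HSD11B2 did not (2.25 ± 0.53, adjusted p = 0.0583), nor did it in a robust fit (adjusted p = 0.0547). STAR, which brings cholesterol into the mitochondrion, averaged 36.9 ± 22.6 and 72.5 ± 25 CPM (0.97 ± 0.34, adjusted p = 0.163), and passed only without control library 6 (adjusted p = 0.0279). An enzyme gene of androgen synthesis, cyp11c1, named after its values were seen, averaged 4.52 ± 2.21 and 12.7 ± 4.93 CPM and did not pass (1.48 ± 0.35, adjusted p = 0.0530), although it was higher adjusted over the list alone. The steroid enzyme genes CYP17A1 (0.80 ± 0.26, adjusted p = 0.128) and hsd3b1 (0.78 ± 0.32, adjusted p = 0.234) did not pass. Neither did CYP11A1 (ENSDARG00000092696) at 0.55 ± 0.21 (adjusted p = 0.200) or CYP11A1 (ENSDARG00000002347) at −0.01 ± 0.17 (adjusted p = 0.975). The luteinizing hormone receptor gene lhcgr averaged 7.28 ± 2.43 and 5.66 ± 1.95 CPM (−0.36 ± 0.26, adjusted p = 0.521). The Leydig list had a median log2 fold change of 0.78 (camera, adjusted p = 0.000152; adjusted p = 0.284 with an estimated correlation). Of 21 steroid hormone synthesis genes, HSD11B2 was the 1 that rose, and 8 were higher and 2 lower adjusted over the list alone. That list passed as a set in camera at the preset correlation (median 0.18, adjusted p = 0.00540). It did not with an estimated correlation (adjusted p = 0.425) or in fry (adjusted p = 0.0580). All Leydig list entries except insl3 and lhcgr also stand in the steroid list, so their results as sets are not independent.

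**Figure D1:**
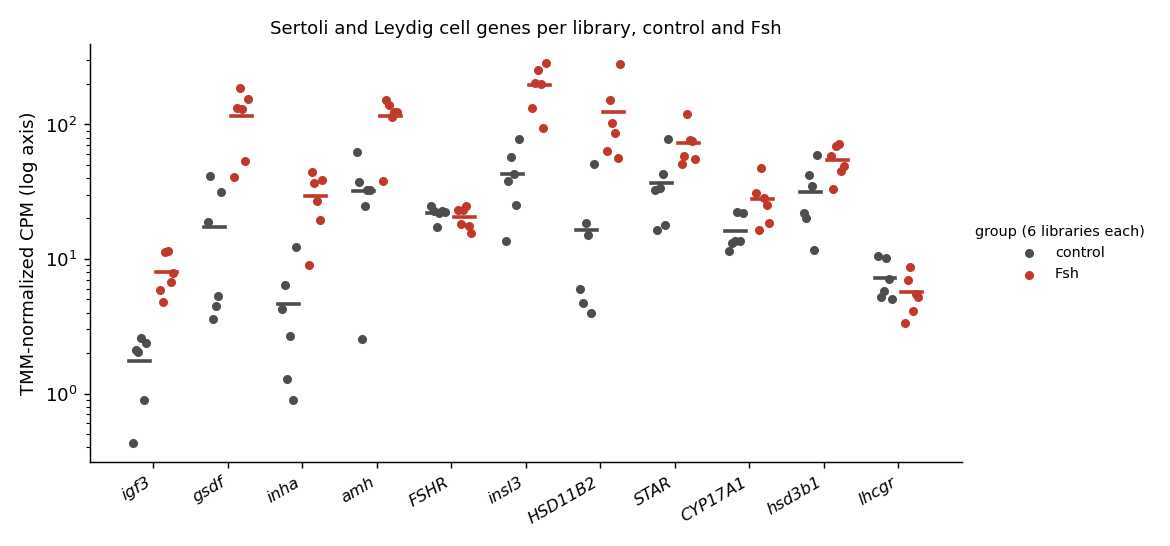
Level of 11 Sertoli and Leydig cell genes in each library, in TMM-normalized CPM on a log axis, with 6 control libraries (grey) and 6 Fsh libraries (red) per gene; each point is a library and the bar is the group mean. The insl3 points average 42.7 CPM in controls and 195 CPM with Fsh, while FSHR averages 22 and 20.4 CPM.

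Of 27 growth and paracrine factor genes, 5 rose, all of them members of the lists above: igf3, insl3, inha, gsdf and INHBA (ENSDARG00000024759), an inhibin beta subunit at 1.12 ± 0.26 (adjusted p = 0.0453). The other copy, INHBA (ENSDARG00000012671), averaged 35.6 ± 29.8 and 23.9 ± 18 CPM and did not pass (−0.58 ± 0.51, adjusted p = 0.603). Adjusted over the list alone, 6 were higher and 1 lower. That list passed as a set (camera, adjusted p = 0.0436; adjusted p = 0.425 with an estimated correlation). It missed the threshold without control library 1, 4, 5 or 6 (adjusted p = 0.0684, 0.127, 0.0503 and 0.119) and without Fsh library 3 or 5 (adjusted p = 0.0713 and 0.328). The call was also lost with library size as the only scaling (adjusted p = 0.0522), with a filter of at least 1 CPM in 6 libraries (adjusted p = 0.0809) and in fry (adjusted p = 0.0850). Of 25 IGF and insulin signalling genes igf3 alone rose, also adjusted over the list alone. The median of that list was −0.02 while its mean was 0.07 and camera pointed up (adjusted p = 0.811).

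The fibroblast and matrix list had a median log2 fold change of 0.48 and passed as a set in camera at the preset correlation (adjusted p = 1.78e-09; adjusted p = 0.284 with an estimated correlation; fry, adjusted p = 0.0427). Of 21 tested, 5 rose, none fell and 16 did not pass, and 9 were higher adjusted over the list alone. COL12A1 (ENSDARG00000019601), a fibril-associated collagen, went from 22.5 ± 5.57 to 62.0 ± 18.1 CPM (log2 fold change 1.46 ± 0.21, adjusted p = 0.00490), and FN1 (ENSDARG00000006526) from 511 ± 152 to 1658 ± 560 CPM (adjusted p = 0.00490). The collagen VI genes col6a1 and COL6A2 rose by 1.07 ± 0.19 and 0.73 ± 0.13 (adjusted p = 0.0137 and 0.0146). Both FN1 and COL12A1 have another copy under the same symbol that did not pass, FN1 (ENSDARG00000019815) at 0.00 and COL12A1 (ENSDARG00000078322) at 0.32. Of 28 genes for extracellular proteases and their inhibitors none passed, although 8 were higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.310). In edgeR 12 of them had an unadjusted p under 0.05, and DESeq2 called 6 and limma-voom 0. MMP15 (ENSDARG00000013072), a membrane metalloproteinase, had the smallest p (0.71 ± 0.17, adjusted p = 0.0548), and passed without control library 2 or Fsh library 1 (adjusted p = 0.0358 and 0.0190).

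The leukocyte list had a median log2 fold change of −0.56, with 19 of 23 members below 0, and passed as a set, downwards, in camera at the preset correlation (adjusted p = 5.99e-05; adjusted p = 0.509 with an estimated correlation; fry, adjusted p = 0.202). Of 23 tested, cd4-1, a helper T cell co-receptor, fell from 3.91 ± 0.73 to 2.00 ± 0.50 CPM (log2 fold change −0.97 ± 0.21, adjusted p = 0.0371), and 2 were lower adjusted over the list alone. The pan-leukocyte gene PTPRC ranged from 25.7 to 77.7 CPM over the controls and from 14.2 to 27.7 CPM over 5 Fsh libraries, and stood at 98.0 CPM in Fsh library 5. Among the 8 largest falls, ifng1 went from 8.90 ± 2.59 to 1.83 ± 1.72 CPM (adjusted p = 0.0446) and tlr18 from 20.1 ± 10.9 to 3.96 ± 1.49 CPM (adjusted p = 0.00780). The chemokine ccl34a.4 fell from 4.35 ± 3.06 to 0.833 ± 0.336 CPM (adjusted p = 0.0197) and ccl34b.4 from 20.4 ± 9.01 to 4.92 ± 2.05 CPM (adjusted p = 0.00821). Without a single library ifng1 missed the threshold in 9 cases (adjusted p up to 0.108), cd4-1 in 7 (up to 0.0920) and ccl34a.4 without Fsh library 2 or 6 (0.0537 and 0.0503). With the leukocyte covariate ifng1, cd4-1 and ccl34a.4 did not pass (adjusted p = 0.117, 0.0815 and 0.0626), and tlr18 and ccl34b.4 did (0.0475 and 0.0435). The log2 fold changes stayed large: from −2.24 ± 0.51 to −1.86 ± 0.55 for ifng1, from −0.97 ± 0.21 to −0.97 ± 0.25 for cd4-1 and from −2.33 ± 0.43 to −2.08 ± 0.50 for ccl34a.4. They went from −2.35 ± 0.37 to −2.22 ± 0.48 for tlr18 and from −2.05 ± 0.33 to −1.59 ± 0.34 for ccl34b.4. Without the low-count filter ifng1 and cd4-1 did not pass (adjusted p = 0.0504 and 0.0596), nor did cd4-1 with library size as the only scaling (adjusted p = 0.0540).

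The other large falls were of unlike kinds. The teneurin gene tenm1, a cell adhesion protein of the nervous system, fell from 22.5 ± 4.94 to 3.10 ± 0.792 CPM (log2 fold change −2.85 ± 0.21, adjusted p = 2.01e-05). The calcium channel subunit gene cacnb2b fell by 2.06 on the log2 scale (adjusted p = 0.00785) and jac2 by 2.73 (adjusted p = 0.0435). The call of jac2 was lost without any 1 of 8 libraries, at adjusted p values up to 0.103, and in limma-voom (adjusted p = 0.0986). PTGES3 (ENSDARG00000089626) had 121 reads over the control libraries and 4 over the Fsh libraries (−4.91 ± 0.41, adjusted p = 3.23e-05). PTGES3 (ENSDARG00000037284), of the same symbol, averaged 68.8 ± 9.34 and 67.8 ± 11.6 CPM, and how reads were divided between the copies is unknown.

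**Figure D2:**
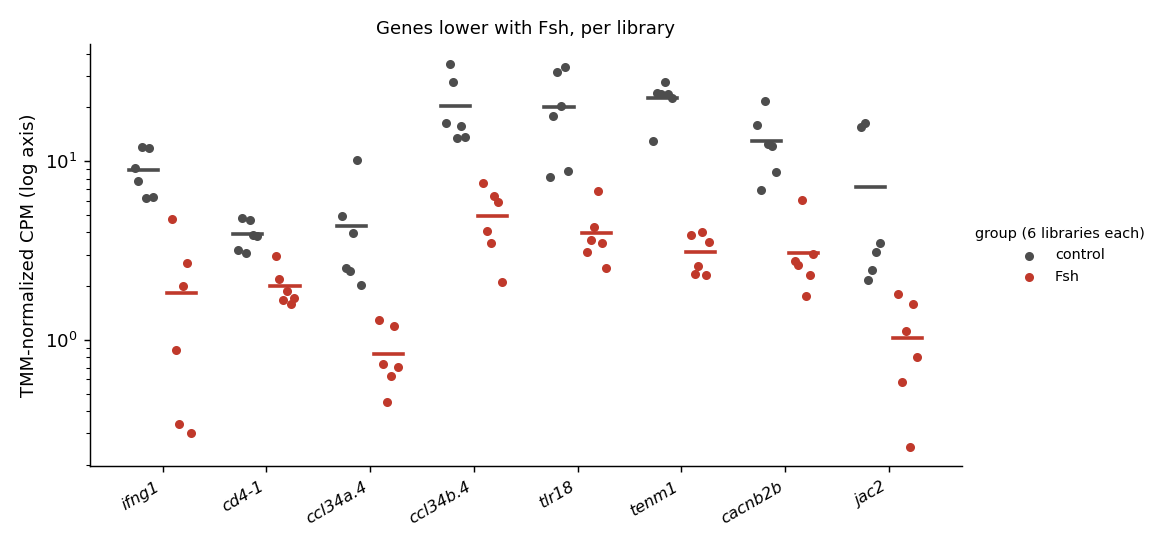
Level of 8 genes that fell with Fsh in each library, in TMM-normalized CPM on a log axis, with 6 control libraries (grey) and 6 Fsh libraries (red) per gene; each point is a library and the bar is the group mean. The tenm1 means are 22.5 and 3.10 CPM and the ifng1 means 8.90 and 1.83 CPM.

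Besides inha, gsdf and HSD11B2, the 8 largest rises held eve1, an even-skipped homeobox gene that went from 0.549 ± 0.441 to 6.58 ± 2.92 CPM (log2 fold change 3.53 ± 0.44, adjusted p = 0.00244). They also held gpx3, a secreted glutathione peroxidase, from 22.8 ± 6.64 to 125 ± 52.4 CPM (2.45 ± 0.29, adjusted p = 0.00159), and ntd5 (2.46 ± 0.31, adjusted p = 0.00244). The others were SLC10A4 (2.61 ± 0.49, adjusted p = 0.0199, and 0.0537 without Fsh library 2) and the water channel AQP1 (ENSDARG00000023713) (2.48 ± 0.53, adjusted p = 0.0347). The call of AQP1 was lost without any 1 of 6 libraries, at adjusted p values up to 0.0853, and in limma-voom (adjusted p = 0.0711). The control means of eve1, SLC10A4 and AQP1 lie near the floor that a count of 0 allows, so their folds are imprecise.

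Signalling lists held single changes. LFNG, a glycosyltransferase that modifies Notch receptors, rose from 14 ± 4.65 to 36.2 ± 8.47 CPM (log2 fold change 1.36 ± 0.21, adjusted p = 0.00705). MAML3, a Notch co-activator, fell by 0.34 (adjusted p = 0.0444), a call lost without any 1 of 9 libraries (adjusted p up to 0.113). Library size as the only scaling, 2 other filters on low counts and leaving out the 50 most abundant genes also ended it, at adjusted p values from 0.0503 to 0.0965. These were the 1 rise and 1 fall among 23 Notch genes, with 1 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.811). BMP7, a bone morphogenetic protein, rose from 3.91 ± 1.52 to 9.99 ± 2.05 CPM (1.34 ± 0.25, adjusted p = 0.0195, and 0.0511 without Fsh library 2). It was the 1 change among 42 TGF-beta and BMP genes, also adjusted over the list alone (camera, adjusted p = 0.161). The 17 Hedgehog genes passed as a set, upwards, in camera at the preset correlation (median 0.24, adjusted p = 0.00854). They did not with an estimated correlation (adjusted p = 0.425) or in fry (adjusted p = 0.0569). No member passed, 4 were higher adjusted over the list alone, and SCUBE2 had the smallest p (0.62 ± 0.20, adjusted p = 0.126, and 0.0435 without control library 6).

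None of the members of 4 other signalling lists passed, nor did any adjusted over the list alone. These were 33 Wnt genes (camera, adjusted p = 0.128; LGR4 at 0.55 ± 0.15), 36 cAMP response genes (adjusted p = 0.811; ADCY1 (ENSDARG00000088634) at 1.14 ± 0.41), 24 retinoic acid genes (adjusted p = 0.863; RXRA (ENSDARG00000035127) at −1.01 ± 0.27) and 9 steroid hormone receptor genes (adjusted p = 0.811; ESR2 (ENSDARG00000016454) at 0.32 ± 0.13). In the same order 7, 3, 6 and 3 members had an unadjusted p under 0.05 in edgeR, DESeq2 called 2, 0, 2 and 0, and limma-voom 0. RXRA passed without Fsh library 5 (adjusted p = 0.0409) and ADCY1 without control library 6 (adjusted p = 0.0465). For the steroid hormone receptors the median of −0.08 and the mean of 0.04 differed in sign.

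Germ cell lists did not pass as sets and held no call over all genes. These were 17 genes of undifferentiated spermatogonia (camera, adjusted p = 0.811), 8 of differentiating spermatogonia (adjusted p = 0.802), 21 of meiosis (adjusted p = 0.310) and 28 of spermatids and the sperm tail (adjusted p = 0.811). Adjusted over the list alone, 2 genes of undifferentiated spermatogonia were lower and the other germ cell lists held no call. In the same order 3, 2, 5 and 2 members had an unadjusted p under 0.05 in edgeR, against 3359 of all 19317 tested genes. DESeq2 called 1, 0, 1 and 1 of them, and limma-voom 0. RET, a receptor of the glial cell line-derived factor family on spermatogonia, averaged 5.90 ± 2.73 and 1.96 ± 0.876 CPM (−1.59 ± 0.38, adjusted p = 0.0530). It passed without control library 2 (adjusted p = 0.0156) or control library 6 (adjusted p = 0.0348). DMRT1 (0.36 ± 0.13), rnf212b (0.88 ± 0.26) and SPATA17 (−0.58 ± 0.17) had the smallest p in the other germ cell lists. Of these rnf212b passed without Fsh library 5 (adjusted p = 0.0232) and SPATA17 without control library 2 (adjusted p = 0.0322). Of 31 cell cycle genes none passed on either count (camera, adjusted p = 0.111; MCM5 at 0.62 ± 0.20), with 8 at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2 or limma-voom. Without Fsh library 5 the meiosis and cell cycle lists both passed as sets, upwards, each at adjusted p = 0.00469, and the cell cycle list also passed without control library 1 (adjusted p = 0.0401).

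**Figure D3:**
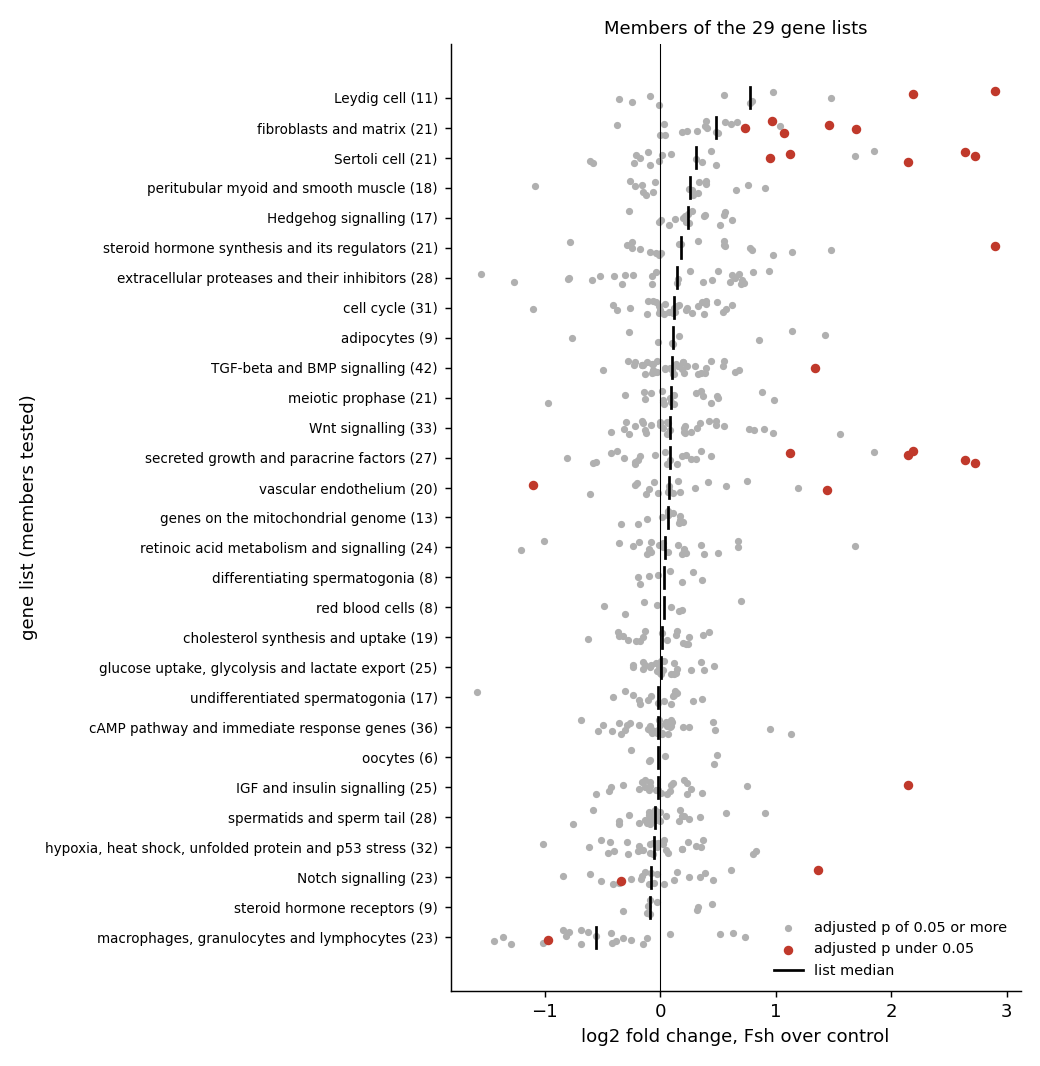
Log2 fold change (Fsh over control) of every tested member of the 29 gene lists, ordered by list median (black bar), with genes at an adjusted p under 0.05 in red and the others in grey; the number of members tested stands in brackets. The Leydig cell list has the highest median, 0.78, and the leukocyte list the lowest, −0.56.

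Among other cell types, endothelial genes went both ways. The gene plvapa, a protein of fenestrated vessels, rose by 1.44 ± 0.29 (adjusted p = 0.0297), and CLDN5 (ENSDARG00000043716), a tight junction protein, fell from 38.0 ± 9.86 to 17.7 ± 6.96 CPM (adjusted p = 0.0491). Both calls were lost without single libraries, that of plvapa in 6 cases (adjusted p up to 0.0804) and that of CLDN5 in 9 (up to 0.115), and that of CLDN5 also without the low-count filter (adjusted p = 0.0554). They were the 2 calls among 20 tested, with 2 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.802). The list named only cldn5b, and the shared symbol brought in both CLDN5 copies. The other copy, CLDN5 (ENSDARG00000014059), averaged 156 ± 33.8 and 103 ± 46.2 CPM and did not pass (−0.60 ± 0.24, adjusted p = 0.207). No smooth muscle gene of 18 passed (camera, adjusted p = 0.225); MYL9 (ENSDARG00000038123), at 0.91 ± 0.23, was the 1 higher adjusted over the list alone. No adipocyte gene of 9 passed (camera, adjusted p = 0.128, and 0.0364 without control library 2), with 3 higher adjusted over the list alone and LPL at 1.14 ± 0.34. No oocyte gene of 6 passed on either count (camera, adjusted p = 0.903; ZAR1 at 0.49 ± 0.31), and there the median of −0.02 and the mean of 0.09 differed in sign. Of 8 red blood cell genes none passed, and cahz (0.70 ± 0.19, adjusted p = 0.0853, and 0.0166 without control library 6) was higher adjusted over the list alone (camera, adjusted p = 0.819). In these 4 lists without a call 5, 4, 0 and 1 members had an unadjusted p under 0.05 in edgeR, DESeq2 called 1, 4, 0 and 1, and limma-voom 0.

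Red blood cell genes took 0.00862% ± 0.00149 of counts in controls and 0.0116% ± 0.00150 with Fsh (exact permutation test, p = 0.0108, adjusted p = 0.0541). Among them cahz went from 45.2 ± 13.9 to 73.4 ± 15.9 CPM. Of the 8 tested members 4 were above 0 and 4 below (median log2 fold change 0.03), so the difference was not shared by the list as a whole. The shares of the 13 protein-coding genes of the mitochondrial genome were 1.30% ± 0.0651 and 1.41% ± 0.116 (exact permutation test, p = 0.0693, adjusted p = 0.173). Mitochondrial rRNA and tRNA genes were not counted in them. Those of the 10 most abundant genes were 19.4% ± 1.78 and 20% ± 0.872 (exact permutation test, p = 0.524, adjusted p = 0.524).

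Metabolic and stress lists held no call on either count. These were 13 genes of the mitochondrial genome (camera, adjusted p = 0.678; MT-ND1 at 0.20 ± 0.09), 25 of glycolysis and lactate export (adjusted p = 0.819; SLC16A1 (ENSDARG00000016963) at 0.38 ± 0.23), 19 of cholesterol synthesis (adjusted p = 0.811; PMVK at −0.62 ± 0.25) and 32 of hypoxia and stress (adjusted p = 0.802; SERPINH1 (ENSDARG00000019949) at 0.83 ± 0.25). In the same order 1, 0, 1 and 8 members had an unadjusted p under 0.05 in edgeR, DESeq2 called 0, 0, 0 and 1, and limma-voom 0. In the cholesterol list the median of 0.02 differed in sign from the mean of −0.03 and the camera direction.

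Single libraries stood apart. On the first principal component (27.1% of the variance) control library 6 lay at 11.5 and the other control libraries between −47.8 and −24.3, while Fsh libraries 1 and 5 lay at 2.05 and −13.1 and the others between 12.3 and 61.8. The count of 315 genes was 169, 149, 112 and 700 without control library 1, 4, 5 or 6, it was 483, 95, 161, 184, 758 and 139 without Fsh library 1, 2, 3, 4, 5 or 6, and DESeq2 called 1087 genes, all 315 included. Of the 29 called genes named here 15 passed whichever library was left out, among them igf3, insl3, FN1 (ENSDARG00000006526), tlr18, ccl34b.4 and tenm1, and the number of lists called did not exceed what other splits of the libraries gave.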

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

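The counts of other splits of the libraries were planned before the data were examined. The 12 libraries can be split into equal groups in 462 ways, of which 100 were drawn, the real split included. No other drawn split gave as many changed genes: the real split gave 315 and the highest other 9. Since 1 of 100 splits, the real one, reached the real count, chance alone is unlikely for the number of genes, though not excluded. For the number of gene lists chance cannot be set aside. There 47 of 100 splits gave as many lists as the 7 of the real split, and the highest other gave 18, with camera at its preset correlation.

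A library stood far from the other 5 of its group, by the gap to its nearest neighbour over the group's range, in 10 of 122 groups of values tested, where chance gives about 6.1. Control library 1 had the lowest tenm1 level, 13.0 CPM against 22.7 to 27.7 in the others. Control library 2 had the highest levels of LFNG, 23.0 CPM against at most 14.7, and of COL6A2, 113 CPM against at most 88.8. Control library 3 had the highest eve1 level, 1.41 CPM against at most 0.613, and control library 5 the highest ccl34a.4 level, 10.2 CPM against at most 4.91. Control library 6 had the highest levels of HSD11B2, 50.7 CPM against at most 18.7, and of PMVK, 49.7 CPM against at most 36.3. Among Fsh libraries, library 1 had the lowest amh level, 37.9 CPM against at least 114. Library 2 had the highest RET level, 3.64 CPM against at most 1.98, and library 3 the highest cacnb2b level, 6.05 CPM against at most 3.02.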

How the results depend on the processing

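The fit with the leukocyte list as covariate was chosen after seeing the data; the other alternatives were planned. The count of changed genes (315) ranged from 262 to 381 under limma-voom, other scalings, other filters on low counts, a robust fit and the replicate number as a block. DESeq2 gave 1087 genes (544 higher, 543 lower) and a test against a 1.5-fold change 18 (10 higher, 8 lower), which by construction asks for more than a difference from 0; the cause of the DESeq2 excess was not tested. Leaving out each library gave 95 to 758 genes, 58 to 373 higher and 37 to 441 lower: 169, 149, 112 and 700 without control library 1, 4, 5 or 6, and 483, 95, 161, 184, 758 and 139 without Fsh library 1, 2, 3, 4, 5 or 6. Fewer libraries give the test less power, while the rise without control library 6 or Fsh library 1 or 5 was not explained by any test. On the first principal component these lay at 11.5, 2.05 and −13.1, towards the other group.

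With the leukocyte covariate 228 genes were called, of which 125 were shared with the 315; 66 were lower, against 148. Of those 148, 44 stayed called, while their median log2 fold change went only from −1.02 to −0.96 and the median standard error from 0.20 to 0.22. With it 13 lists passed, for a cause that was not tested, and the leukocyte list itself turned upwards at adjusted p = 0.956, which its own use as covariate brings about. The 7 lists became 0 in camera with an estimated correlation, where 3 of 29 had an unadjusted p under 0.05, and 3 in fry (the Sertoli, Leydig and fibroblast lists), while 17 passed in the mixed test of fry. Lists that camera did not call were among the 17: Notch (mixed fry, adjusted p = 1.30e-05), IGF and insulin (4.69e-05), proteases (0.000125), Wnt (0.000252) and retinoic acid (0.000773), for example. The mixed test does not compare a list with other genes. In the other settings, libraries left out included, between 6 and 8 lists passed.

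The replicate block gave 381 genes, 214 shared with the 315, and among the named genes it ended the calls of MAML3 (adjusted p = 0.0924) and cd4-1 (adjusted p = 0.0627). Equal numbers correlated at 0.02 to 0.26 in their deviations from the group means, above 0.1 for 4 of 6 numbers, against a median of −0.07 for unequal numbers, and 5 of 12 libraries correlated best with their own number. Pairing by number was thus seen in part of the libraries, a hint from the data and not from the design, and was not used. Of the 29 called named genes all kept their call in DESeq2 and with RLE size factors, 27 in limma-voom, with library size only and in the robust fit, 25 without the low-count filter, 19 with the leukocyte covariate and 5 against a 1.5-fold change; none changed sign. The calls ended were AQP1 (ENSDARG00000023713) and jac2 in limma-voom, cd4-1 and MAML3 with library size only, gsdf and HSD11B2 in the robust fit, and cd4-1, MAML3, ifng1 and CLDN5 (ENSDARG00000043716) without the low-count filter, for causes that were not tested. The call of MAML3 also ended without the 50 most abundant genes and with the filter of at least 1 CPM, and that of the growth factor list with library size only, with that filter and in fry. The covariate ended the calls of inha, gsdf, HSD11B2, SLC10A4, ifng1, ccl34a.4, cd4-1, jac2, MAML3 and CLDN5 (ENSDARG00000043716), at adjusted p values from 0.0557 (SLC10A4) to 0.132 (jac2). Of the 27 named genes not called in the main fit, DESeq2 called 11, the fit with the covariate 2 and library size only 1. DESeq2 called 6 members of the Sertoli list and 3 of the Leydig list. The largest shift of the median of all genes under another scaling was 0.03 (log2). FN1 (ENSDARG00000006526) has no value without the 50 most abundant genes, being among them. Correction for GC content and length was not run, since no annotation of these gene IDs was used here. Depth limits the weakest genes: 3 counts are 0.641 CPM in control library 1 and 0.259 CPM in Fsh library 1.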

Other observations

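All tests in this part were chosen only after the results were seen. Genes were grouped by the letters that open their symbol, in 195 families of at least 10 tested genes, and each family was tested for called genes in each direction (one-sided Fisher's exact test, 390 tests). Only 2 tests passed, and their p values take genes as independent, which genes of a family need not be. Of 10 chemokine genes of the ccl family 4 fell, against 81 of all 13584 genes with such a symbol (adjusted p = 9.35e-05): ccl34b.4, ccl34a.4, ccl19a.1, from 749 ± 243 to 357 ± 97.1 CPM, and ccl25b, from 335 ± 128 to 110 ± 59.1 CPM. Of 40 collagen genes 6 rose, against 132 of 13584 (adjusted p = 0.000429): besides COL12A1, col6a1 and COL6A2 these were col18a1a, from 115 to 232 CPM, col4a5, from 33.1 to 127 CPM, and col28a2a, from 3.01 ± 1.02 to 39.0 ± 42.0 CPM and higher in 5 of 6 Fsh libraries. COL14A1 fell, from 29.7 to 13.2 CPM.

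Some single genes, singled out after their values were seen, stood beside these. IHH, a gene for an Indian hedgehog ligand, rose by 1.55 (adjusted p = 0.0297), and SCUBE1 by 1.68 (adjusted p = 0.00486). The fixed Hedgehog list named ihha and ihhb, but the gene called IHH was not among its tested members. Their largest log2 fold change was 0.62. IDH1, a cytosolic NADP-dependent dehydrogenase, rose by 1.32 (adjusted p = 0.00104), the chloride channel gene CFTR by 1.29 (adjusted p = 0.00244) and the hypoxia-inducible factor gene EPAS1 (ENSDARG00000008697) by 1.69 (adjusted p = 0.00575), while the other copy, EPAS1 (ENSDARG00000057671), was at 0.18. HNMT, which inactivates histamine, rose from 1.68 to 19.2 CPM (adjusted p = 0.00780) and was higher in 5 of 6 Fsh libraries.

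The higher Sertoli and Leydig cell genes may reflect regulation within these cells or a larger share of them. The list medians of 0.31 and 0.78 lay below those of the called members, 2.14 and 2.54, and 8 of 21 Sertoli and 4 of 11 Leydig cell genes were below 0. How far other testis cells also express these genes was not measured, so a larger share cannot be told apart from regulation. Counts taken by a few abundant genes are argued against: the share of the 10 most abundant genes ran from 18% to 22.7%, which can shift other genes by at most 0.0845 on the log2 scale between any 2 libraries, while the smallest change of a called member was 0.95. A direct effect of Fsh on these genes remains as a hypothesis, which was not tested against an effect through other cells.

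An immune list, drawn up after the results had been seen, held 209 tested genes, 15 of which fell and none rose: 200 found by the opening letters of their symbols (cytokines, chemokines and their receptors, interferon, NF-kappa-B and Toll-like receptor genes, suppressors of cytokine signalling and surface antigens among them) and 9 T and NK cell genes added singly, of which tbx21 and EOMES fell. Of the 200 alone 13 fell, and 9 of 190 without the ccl family, against 90 of 15142 other named genes (one-sided Fisher's exact test, p = 8.14e-10 and 3.78e-06, too small by an unknown amount since genes were taken as independent and the classes were chosen after the falls were seen); camera with an estimated correlation passed for neither (p = 0.0615 and 0.0719). Fewer leukocytes could be the cause: with the leukocyte list as covariate 20% of the 15, that is ifi44a1, tlr18 and ccl34b.4, stayed called, while the median log2 fold change of the 15 went from −1.16 to −0.97, so that most of the calls ended although most of the fold remained, and this explanation cannot be told apart from lower expression per cell. Fewer T and NK cells could be another: the median of 14 of their markers, 3 of them in the leukocyte list, was −0.78. The most abundant, nkl.2, stood at 31.6 CPM in controls and 14.4 CPM with Fsh, while il7r and gzmk were at −0.25 and −0.35. The mean log2 CPM of the 14 differed by −0.84 with Fsh (exact permutation test, two-sided, p = 0.00433) and that of the 10 not called by −0.63 (p = 0.0216). The markers were chosen after the falls were seen and 4 of them were called genes, so these p values cannot be read as those of a planned test. A fall in cytokine signalling within these cells stays open as well, untested.

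A few genes were separated almost completely between the groups. In 9 genes every library of the higher group had at least 0.5 CPM. Each such library also had more than 2 times the level of every library of the other group. This count was reached by 1 of 100 splits, the real one (highest other 2). The rule for such genes was set after the values were seen, so the splits do not exclude chance for their number. The smallest p of all genes belonged to ENSDARG00000083325, which has no symbol in the table used: 69.0 ± 5.21 CPM in controls and 17.9 ± 2.05 CPM with Fsh (log2 fold change −1.95 ± 0.10, adjusted p = 3.48e-07), while ENSDARG00000091629 had 901 reads over the controls and 28 over the Fsh libraries. For PTGES3 (ENSDARG00000089626), reads may have moved to the other copy, but the change of that copy, −1.02 CPM, lies within its SD of 10.5 CPM, so a shift of the 2.56 CPM lost by the first cannot be seen there and this explanation cannot be told apart from lower expression.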
